A study of Mus musculus with 18 samples.

How the data were processed

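The series holds RNA sequencing of sorted mouse Treg cells from 6 genotypes with 3 libraries each. The submitters' notes name total RNA extraction with small RNAs kept, TruSeq RNA libraries and an Illumina HiSeq instrument. The authors deposited 1 table of RPKM values (reads per kilobase of transcript, scaled to the mapped reads of the library) with a column for each of the 18 libraries. Their notes name STAR 2.2.0c, HOMER and the genome build mm10 (GRCm38), without saying which step made the RPKM values or with which annotation. Read counts were not used here. The depth was estimated from the steps between RPKM values of 3310 genes with a single transcript, which gave 20.96 to 31.68 megareads per library. Between replicates, the median chi-square of a pair of libraries was 4.36 to 17.0 times that of counting error alone, so the spread between libraries, and not counting error, set the precision.

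The table held 23953 entries. Of these, 4 with a repeated symbol were left out, 27 had symbols turned into dates, and 5198 were listed at 0 in all 18 libraries. Symbols were matched to GENCODE directly for 22635 entries and by a synonym for a further 922, to give locations and 3' UTRs. Tables were read with Python 3.11.15 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and tests were run in R 4.3.3 with limma 3.58.1. Genes with at least 1 RPKM in at least 3 libraries were tested (11520 genes), on log2(RPKM + 0.5). A single limma model with a mean-variance trend covered the 18 libraries, with a prior of 2.26 degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p, two-sided and within the comparison, was under 0.05. The comparisons were the 5 of each genotype with WT, and miR-27 Tg with miR-23 Tg, miR-27 Tg with miR-24 Tg, cluster Tg with miR-27 Tg and cluster Tg with DKO.

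Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 of 31 lists that had at least 5 tested genes. Their themes were Treg identity, effector Treg, resting T cell, Treg suppression, NF-kB, TCR-induced, Th1, Th2, Th17, follicular T cell, cell cycle, interferon response, TGF-beta signalling, apoptosis, migration receptors, glycolysis, cholesterol synthesis, ribosomal proteins, literature targets of miR-23, miR-24 and miR-27, and miRNA cluster loci. Further lists held markers of B cells, plasma cells, CD8 T cells, myeloid cells, NK cells, erythroid cells or platelets, conventional CD4 activation, dissociation or stress, and sex-linked genes. Camera with an estimated correlation and fry were run beside it. Seed sites were matches in annotated 3' UTRs of at least 50 bases to AATGTGA (miR-23), CTGAGCC (miR-24) or ACTGTGA (miR-27), over 10584 genes, and the 15 camera tests were adjusted together. Site genes were also compared with 10000 random lists matched on 3' UTR length and expression, with a smallest possible p of 2e-04 before adjustment, and with 100 control heptamers per site. Shares of called genes with a site were compared by Fisher's exact test, two-sided. Single loci were compared by exact permutation of the libraries, two-sided. Correlations of fold changes were set beside 100 simulations of unchanged groups that shared the WT libraries.

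Named genes followed a rule. For each comparison with WT they were the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, without predicted, clone, small RNA or antigen receptor segment symbols. Where under 3 genes passed in a direction, the 3 with the smallest unadjusted p were named as not passing. Further named genes were a fixed panel (Foxp3, Il2ra, Ctla4, Ikzf2, Il10, Rel, Gata3), up to 4 genes per list by smallest p, 5 rises and 5 falls per direct comparison, and 5 site genes per seed test. A few other genes of the lists are given as values beside these. The model, lists, rule and the following alternatives were chosen before the data were examined: a pseudocount of 0.1 or 1, no filter, median-of-ratios scaling, only the 2 compared groups in the fit, the replicate number as a block, leaving out each library, an estimated correlation, fry, an 8-base match, the matched background and a minimum mean of 5 RPKM for the correlations. Alternatives added later were covariates for sex, for B cell genes and for immediate-early genes, leaving out small RNA entries, and leaving out the 2 libraries with the highest B cell and myeloid markers (miR-24 Tg library 1 and miR-27 Tg library 3). The replicate number was not used as a pairing in the main model. Over 45 pairs of libraries of different groups that shared it, the correlation had a median of 0.004 and ran from -0.167 to 0.188, with 6 pairs over 0.1, of which 5 had number 3. Some shared structure is therefore not ruled out, and with the number as a block more genes passed in each comparison except DKO against WT. The method was tested on simulated data built from the miR-27 Tg and WT libraries.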

Results

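RNA was sequenced from regulatory T (Treg) cells, sorted from C57BL/6 mice as CD4-positive cells with high CD25. There were 6 genotypes with 3 libraries each, 18 libraries in all. In 4 groups T cells overexpressed microRNAs of the miR-232724 cluster: miR-23 alone (miR-23 Tg), miR-24 alone (miR-24 Tg), miR-27 alone (miR-27 Tg) or the 3 together (cluster Tg). DKO cells lacked the miR-23a and the miR-23b cluster through deletion in T cells, and WT cells were the control. The deposited values were RPKM, and the steps between their low values put the depth at 20.96 to 31.68 megareads per library, with 10710 to 11121 genes at 1 RPKM or more. The labels do not say that the libraries came from separate animals, so the p-values below measure the spread between these samples. Values are mean RPKM ± SD with n = 3 per group, the first group of a comparison first, and folds come from limma on log2(RPKM + 0.5). Adjusted p is the Benjamini-Hochberg value over 11520 genes, or over 29 gene lists, in each comparison, and the tests were two-sided.

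The first question was whether each group had reads at the microRNA loci of its genotype. Such reads do not measure the mature microRNAs, which the library protocol may not capture. The miR-23a cluster lies on chromosome 8 of mm10 (Mir23a 84208518 to 84208592, Mir27a 84208672 to 84208758, Mir24-2 84208815 to 84208921). Mir23a reached 33620 ± 4041 RPKM in miR-23 Tg and 17230 ± 5606 in cluster Tg, against 72.2 ± 78.0 in WT, and was listed at 0 in each DKO library. Mir27a reached 68700 ± 16220 in miR-27 Tg and 18690 ± 5194 in cluster Tg, against 164 ± 174 in WT, and was likewise listed at 0 in each DKO library. Mir24-2 reached 13500 ± 7722 in miR-24 Tg and 6803 ± 1004 in cluster Tg, against 16.8 ± 29.0 in WT and 3.82 ± 6.62 in DKO. In these 6 contrasts with WT no library of one group overlapped the other, with a two-sided exact permutation p of 0.1, the lowest that 3 against 3 libraries can give. In the groups that did not overexpress them, Mir23a stood at 304 ± 458 in miR-24 Tg and 195 ± 92.4 in miR-27 Tg. Mir27a stood at 153 ± 57.0 in miR-23 Tg and 338 ± 318 in miR-24 Tg, and Mir24-2 at 32.4 ± 3.89 in miR-23 Tg and 20.1 ± 25.6 in miR-27 Tg. Against WT, Mir23a and Mir27a in DKO had a two-sided exact p of 0.4 each, because a WT library was also listed at 0. Of the miR-23b cluster, Mir23b, Mir27b and Mir24-1 stood at 0.00771 RPKM or less in each library, WT included. The loss of that cluster in DKO could therefore not be checked at these loci.

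**Figure D1:**
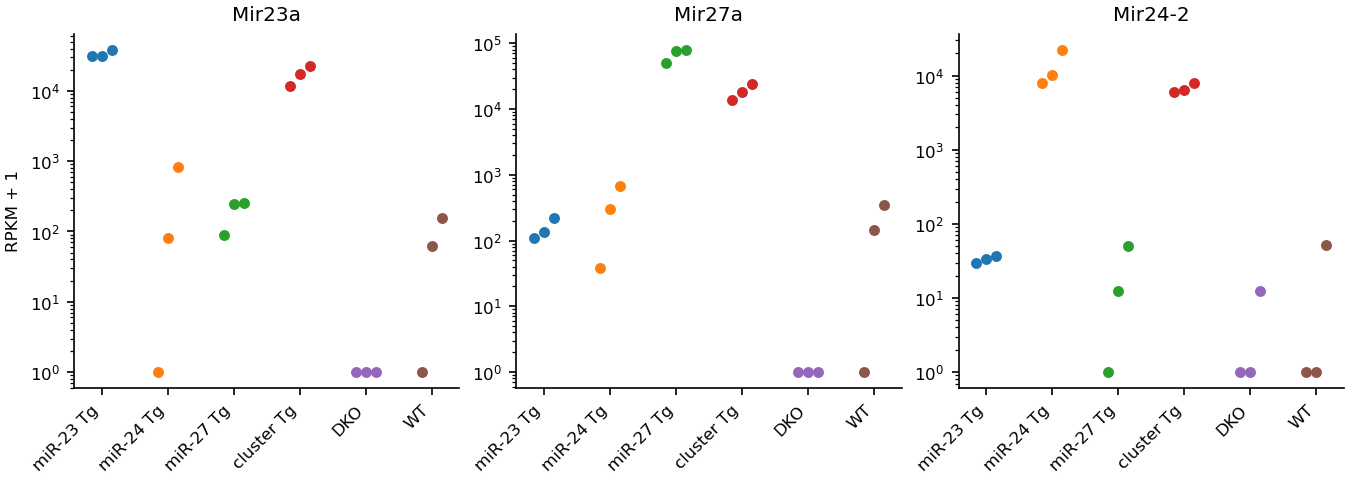
RPKM + 1 (log axis) of Mir23a, Mir27a and Mir24-2 by group, with a point per library sorted by value within its group. Mir23a lies at a mean of 33620 in miR-23 Tg, Mir27a at 68700 in miR-27 Tg and Mir24-2 at 13500 in miR-24 Tg.

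The comparison of miR-23 Tg with WT asked what overexpression of miR-23 alone did to Treg cells. Cytokine gene Il21 rose 3.48-fold (8.78 ± 2.32 against 2.19 ± 0.757, adjusted p = 0.0493), and Dapl1, found in resting T cells, rose 2.96-fold (28.6 ± 7.26 against 9.56 ± 3.72, adjusted p = 0.0308). The long noncoding RNA Gt(ROSA)26Sor, on chromosome 6 from 113067428 to 113077333, fell by 1.40 on the log2 scale (5.54 ± 0.534 against 15.6 ± 2.89, adjusted p = 0.0203), and the Treg gene Ecm1 fell 1.59-fold (87.1 ± 2.88 against 140 ± 24.4, adjusted p = 0.0269). In all, 18 genes were higher and 23 lower, 8 and 1 of them by at least 2-fold, and 1567 genes had an unadjusted p under 0.05. The other large rises were those of phosphodiesterase gene Pde3b (3.3-fold; 7.09 ± 2.13 against 1.76 ± 0.409), Lsr (2.34-fold; 5.14 ± 0.330 against 1.91 ± 0.130), Stc2 (2.33-fold), Cep170b (1.82-fold) and semaphorin gene Sema4f (1.81-fold, adjusted p = 0.0203). Embryonic globin gene Hbb-bh1 was listed at 0 in each WT library and at 2.43 ± 0.0989 in miR-23 Tg (adjusted p = 0.00488). The other large falls were those of prostacyclin receptor gene Ptgir (1.89-fold, adjusted p = 0.0382), Rasip1 (1.79-fold), Zfp937 (1.7-fold), She (1.67-fold), Zfp874a (1.62-fold) and Sft2d1 (1.61-fold; 5.15 ± 0.333 against 8.57 ± 0.519). Without any 1 of the 6 libraries, 1 to 3 genes each way were left, so most of these calls rest on the full set. With the level of B cell genes as a covariate 2 genes were higher and 1 lower. The 38 calls that ended kept their sign, with a median absolute log2 fold change of 0.642 (0.729 before) and a median standard error of 0.171 (0.128 before), so the drop does not show that B cells explain them. With sex, read from X- and Y-linked genes, as a covariate 8 were higher and 12 lower, and the 22 calls that ended had a median absolute log2 fold change of 0.678 (0.684 before) and a median standard error of 0.131 (0.124 before).

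By lists, 45 cell cycle genes had a median log2 fold change of 1.08 in miR-23 Tg, and none of the 45 passed over all genes, while 41 were higher when adjusted over the list alone. The list had adjusted p = 2.08e-24, and adjusted p = 0.318 with an estimated correlation. Proliferation marker Mki67 stood at 24.3 ± 1.77 against 9.31 ± 3.22 (adjusted p = 0.092), Ccna2 at 18.7 ± 1.64 against 4.91 ± 1.94 (adjusted p = 0.0881) and Ube2c at 24.6 ± 1.85 against 5.60 ± 2.63 (adjusted p = 0.118). Markers of other cells were high in the same libraries: 17 B cell genes had a median of 1.49 (adjusted p = 3.68e-11, and adjusted p = 0.318 with an estimated correlation), and 13 were higher when adjusted over the list alone. Myeloid gene Lyz2 stood at 14.9 ± 6.82 against 2.36 ± 0.565 (15 myeloid genes, median 1.06, adjusted p = 7.27e-06, and adjusted p = 0.428 with an estimated correlation). For 6 NK cell genes the median was 0.63 (adjusted p = 0.0205, and adjusted p = 0.496 with an estimated correlation). The 17 Th1 genes had a median of 0.57 (adjusted p = 5.56e-05, and adjusted p = 0.374 with an estimated correlation), with Tbx21 at 6.00 ± 0.470 against 2.91 ± 0.0469 and Cxcr3 at 39.5 ± 4.45 against 20.4 ± 3.51. Among 28 Treg identity genes 1 fell (Ecm1) and 27 did not pass, and Ikzf4 stood at 25.1 ± 3.98 against 41.2 ± 2.85. Their median was -0.20 (adjusted p = 0.000767, and adjusted p = 0.318 with an estimated correlation). The 43 interferon response genes had a median of -0.20 (adjusted p = 5.78e-06, and adjusted p = 0.478 with an estimated correlation), with Oas2 at 3.27 ± 0.726 against 5.32 ± 0.835.

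The comparison of miR-24 Tg with WT asked the same of miR-24. Treg receptor gene Gpr83, on chromosome 9 from 14860210 to 14870789, fell 6.88-fold (12.6 ± 4.47 against 87.0 ± 22.6, adjusted p = 0.000296), and Ecm1, on chromosome 3 from 95734147 to 95739569, fell 4.3-fold (32.0 ± 1.95 against 140 ± 24.4, adjusted p = 3.95e-07). Chemokine genes Xcl1 and Ccl1 rose 6.39-fold (46.5 ± 9.15 against 7.12 ± 2.62, adjusted p = 0.00167) and 5.67-fold (29.2 ± 10.4 against 4.58 ± 0.696, adjusted p = 0.000666). A total of 530 genes were higher and 504 lower, 130 and 61 of them by at least 2-fold. Without any 1 of the 6 libraries 264 to 470 were higher and 255 to 377 lower, and with only these 2 groups in the fit 284 and 271. The largest rises were those of J chain gene Igj (8.82-fold; 10.4 ± 10.3 against 0.454 ± 0.341, adjusted p = 0.0434), Ly6c2 (6.5-fold; 14.6 ± 5.44 against 1.77 ± 0.660), Xcl1, Ccl1, NK receptor gene Klrd1 (5.63-fold; 3.65 ± 1.97 against 0.168 ± 0.0838), lysozyme gene Lyz2 (5.16-fold; 21.6 ± 24.3 against 2.36 ± 0.565, adjusted p = 0.0443), chemokine gene Ccl3 (4.91-fold; 4.81 ± 4.58 against 0.352 ± 0.0435) and keratin gene Krt17 (4.67-fold, adjusted p = 0.000845). Besides Gpr83 and Ecm1 the largest falls were those of Igsf23 (5.33-fold; 3.29 ± 1.08 against 19.4 ± 3.19), P-selectin gene Selp (4.88-fold), Khdc1a (4.75-fold), Gabrr2 (4.44-fold; 1.76 ± 0.613 against 9.31 ± 1.08), cohesin gene Rec8 (4.04-fold, adjusted p = 0.0021) and Rasip1 (3.74-fold, adjusted p = 7.25e-06). The calls of Igj, Klrd1, Lyz2 and Ccl3 ended when miR-24 Tg library 1, which had the highest Lyz2 value of the group (49.5), was left out. In libraries 2 and 3, Klrd1 stood at 4.58 and 1.38, Igj at 3.46 and 5.39 and Lyz2 at 5.73 and 9.44, each above every WT library. For these genes the lost calls do not show that library 1 alone carried the rise. With the B cell covariate the counts were 232 higher and 214 lower. The 636 calls that ended had a median absolute log2 fold change of 0.484 (0.517 before) and a median standard error of 0.172 (0.129 before).

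Of 34 effector Treg genes 18 rose and 16 did not pass in miR-24 Tg: Icos by 1.85-fold (165 ± 5.30 against 88.9 ± 4.15), Fgl2 by 2.46-fold (23.2 ± 5.14 against 9.05 ± 1.06), Itgb1 by 2.21-fold and Maf by 1.88-fold (87.4 ± 17.9 against 45.7 ± 2.01). The list had a median of 0.87 and adjusted p = 6.48e-12, and adjusted p = 0.252 with an estimated correlation. Of 28 Treg identity genes 8 fell and 1 rose, among the falls Swap70 (2.2-fold; 14.1 ± 1.78 against 31.5 ± 1.91) and Plagl1 (3.69-fold; 1.49 ± 0.0539 against 6.84 ± 0.390), with adjusted p = 6.66e-05 for the list (adjusted p = 0.252 with an estimated correlation). Th1 genes rose in 8 of 17 cases, with Il18r1 3-fold higher (88.6 ± 19.8 against 29.0 ± 5.13), Ccl5 4.55-fold (79.6 ± 15.7 against 17.4 ± 5.52) and Cxcr3 2.89-fold, and the list had adjusted p = 8.05e-08 (adjusted p = 0.252 with an estimated correlation). Of 22 resting T cell genes 5 fell, such as Tcf7 (1.54-fold; 182 ± 19.8 against 279 ± 9.74), and 2 rose, of which Dapl1 by 4.59-fold, with adjusted p = 0.000419 (adjusted p = 0.259 with an estimated correlation). Suppression genes rose in 4 of 18 cases and fell in 1, the latter Lrrc32 by 1.82-fold (adjusted p = 0.00821 for the list, and adjusted p = 0.252 with an estimated correlation). T cell receptor signalling gene Cd5 fell 1.53-fold (217 ± 4.89 against 333 ± 18.6), and survival gene Mcl1 fell 1.36-fold. In the same libraries 8 of 17 B cell genes were higher (17 when adjusted over the list alone; median 1.49, adjusted p = 1.69e-09, and adjusted p = 0.269 with an estimated correlation), with Cd22 at 7.10 ± 2.62 against 1.87 ± 0.136. Of 15 myeloid genes 3 were higher (adjusted p = 1.17e-05, and adjusted p = 0.337 with an estimated correlation). The cell cycle list also passed upward at the preset correlation, though not with an estimated one, and its median turned negative with the B cell covariate. Mki67 stood at 20.85, 12.53 and 25.13 in miR-24 Tg libraries 1 to 3, against 5.69, 11.84 and 10.41 in WT. When adjusted over the list alone, 20 effector Treg genes and 9 Th1 genes were higher, 11 Treg identity genes were lower and 3 higher, 10 resting T cell genes were lower and 2 higher, and 7 suppression genes were higher and 1 lower.

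**Figure D2:**
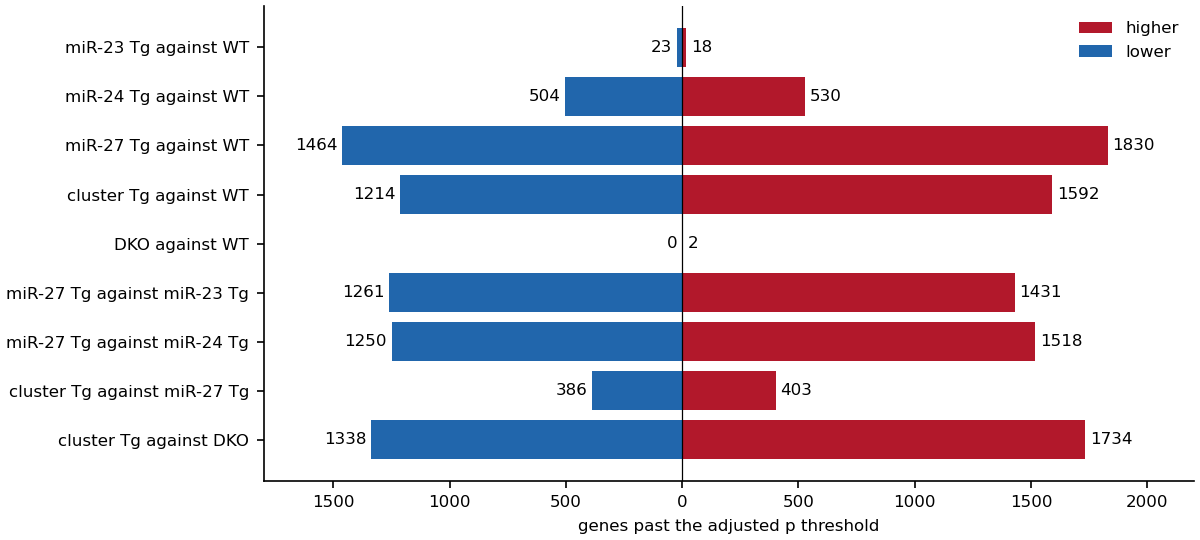
Number of genes past the adjusted p threshold of 0.05 in each of the 9 comparisons, as bars for genes higher and genes lower in the first group. The bars run from 0 lower genes for DKO against WT to 1830 higher genes for miR-27 Tg against WT.

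The comparison of miR-27 Tg with WT asked what miR-27 alone did. Integrin gene Itgam, on chromosome 7 from 128062640 to 128118491, rose 13.0-fold (13.8 ± 2.12 against 0.601 ± 0.170, adjusted p = 5.38e-06), and Mki67 rose 6.15-fold (62.1 ± 26.7 against 9.31 ± 3.22, adjusted p = 0.000128). Death receptor gene Fas fell 2.39-fold (22.4 ± 1.25 against 54.2 ± 0.599, adjusted p = 7.8e-07) and Ppif, the gene of mitochondrial cyclophilin D, fell 2.63-fold (9.07 ± 1.004 against 24.6 ± 1.35, adjusted p = 8.23e-07). Zbtb10, named in the literature as a miR-27 target, fell 4.05-fold (0.516 ± 0.237 against 3.65 ± 1.11, adjusted p = 0.000275). Its annotated 3' UTR held no match to the miR-27 site used here and 1 to the miR-23 site. The counts were 1830 higher and 1464 lower, 612 and 129 of them by at least 2-fold. The largest rises were those of Igj (23.6-fold; 36.3 ± 41.2 against 0.454 ± 0.341, adjusted p = 0.00203), Itgam, Klrd1 (9.66-fold), plasma cell gene Mzb1 (8.59-fold; 8.46 ± 8.61 against 0.228 ± 0.136), protease inhibitor gene Slpi (8.04-fold), Pdlim4 (7.64-fold, adjusted p = 0.000195), galectin gene Lgals7 (7.1-fold; 19.9 ± 10.5 against 2.10 ± 0.520) and mitotic gene Ube2c (7.08-fold; 45.3 ± 24.3 against 5.60 ± 2.63). The largest falls were those of troponin gene Tnnt2 (4.86-fold; 0.564 ± 0.120 against 4.80 ± 1.53), Snhg9 (4.78-fold), glutathione transferase gene Gsta4 (4.65-fold; 8.79 ± 1.45 against 43.0 ± 9.24), Arhgap20 (4.62-fold), Sh3bgrl2 (4.6-fold; 1.53 ± 0.246 against 8.79 ± 0.250), Zbtb10, Gt(ROSA)26Sor (4.04-fold, adjusted p = 6.03e-05) and Scg5 (4.01-fold). With the B cell covariate 454 genes were higher and 276 lower, and Igj, Klrd1, Mzb1, Slpi, Ube2c and Snhg9 no longer passed. The 2588 calls that ended had a median absolute log2 fold change of 0.407 (0.51 before) and a median standard error of 0.194 (0.131 before), so the loss alone does not show that B cells explain them.

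Each of the 45 cell cycle genes rose in miR-27 Tg, with a median of 1.96: Ccna2 by 6.63-fold (37.1 ± 18.1 against 4.91 ± 1.94) and Kif4 by 4.54-fold (8.50 ± 3.69 against 1.38 ± 0.413). That list had adjusted p = 7.51e-20, and adjusted p = 0.37 with an estimated correlation. The libraries were uneven, with Mki67 at 31.9, 82.7 and 71.7 in libraries 1 to 3, whose B cell scores were -0.1, 1.17 and 1.89. With the B cell covariate 1 of the 45 genes still passed, and the median was 1.24. Effector Treg genes rose in 29 of 34 cases and fell in 1, with Maf 2.93-fold higher (135 ± 2.40 against 45.7 ± 2.01), Ccr4 3.44-fold (85.5 ± 7.98 against 24.6 ± 3.62), Irf4 1.63-fold and Icos 1.97-fold (adjusted p = 5.04e-12, and adjusted p = 0.37 with an estimated correlation). Interferon response genes rose in 27 of 43 cases, among them Ifih1 by 2.28-fold (20.2 ± 1.51 against 8.59 ± 0.221), Oas2 by 3.6-fold and Ifi204 by 7.06-fold (adjusted p = 2.5e-10, and adjusted p = 0.37 with an estimated correlation). Of 15 Th17 genes 10 rose, with Ccl20 5.58-fold higher (11.8 ± 3.53 against 1.74 ± 0.788), Tmem176a 5.18-fold and Ahr 2.84-fold (adjusted p = 1.68e-05, and adjusted p = 0.37 with an estimated correlation). The 13 follicular T cell genes included 8 rises, such as Angptl2 by 4-fold (50.3 ± 2.37 against 12.2 ± 0.730) and Il21 by 3.86-fold (adjusted p = 1.33e-05, and adjusted p = 0.188 with an estimated correlation). Ribosomal protein genes fell in 29 of 37 cases, Rpl23 by 1.86-fold (120 ± 4.97 against 223 ± 7.88), with a median of -0.62 (adjusted p = 1.02e-12, and adjusted p = 0.37 with an estimated correlation). Resting T cell genes fell in 11 of 22 cases, such as Ccr7 by 1.76-fold (98.5 ± 8.76 against 174 ± 5.47) and Bach2 by 1.91-fold (adjusted p = 0.000183, and adjusted p = 0.37 with an estimated correlation). When adjusted over the list alone, 45 cell cycle, 29 interferon response, 11 Th17 and 9 follicular T cell genes were higher, and 30 ribosomal protein and 12 resting T cell genes were lower.

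Treg identity genes were split in miR-27 Tg, with 2 of 28 higher (Socs2 by 2.2-fold) and 6 lower (Ikzf1 by 1.39-fold, Satb1 by 1.67-fold), and the list did not pass (adjusted p = 0.0804). The Treg transcription factor gene Foxp3, on chromosome X from 7573644 to 7595245, stood at 271 RPKM in miR-27 Tg against 319 in WT (adjusted p = 0.262). It passed in no comparison with WT, at 236 in miR-23 Tg, 271 in miR-24 Tg, 249 in cluster Tg and 327 in DKO. The other panel genes Il2ra, Ctla4, Ikzf2, Il10, Rel and Gata3 passed in no comparison with WT either, with the lowest adjusted p for Ikzf2 in miR-23 Tg (69.8 ± 12.8 against 103 ± 7.25, adjusted p = 0.118). Apoptosis genes rose in 6 and fell in 5 of 26 cases. The median and mean of that list lay above 0 while its test pointed down (adjusted p = 0.681). Of 22 reported miR-27 targets 6 fell (Zbtb10; Cblb by 1.76-fold, 15.7 ± 1.36 against 27.9 ± 1.71) and 3 rose, such as Rxra by 1.67-fold, with a list adjusted p of 0.223. Th1 genes rose in 9 of 17 cases and fell in 1, with Gzmk 6.99-fold higher and Ifngr1 1.53-fold lower (adjusted p = 0.00195, and adjusted p = 0.441 with an estimated correlation). Markers of other cells moved in the same libraries. Of 17 B cell genes 16 were higher (list adjusted p = 1.17e-07, and adjusted p = 0.37 with an estimated correlation). Of 15 myeloid genes 7 were higher, with Lyz2 at 18.1 ± 12.8 against 2.36 ± 0.565 (adjusted p = 0.000466, and adjusted p = 0.481 with an estimated correlation), and of 6 NK cell genes 4 were higher and 1, Prf1, lower (adjusted p = 0.0804). Immediate-early gene Jun was lower (88.6 ± 58.7 against 272 ± 92.1, adjusted p = 0.0285), and Fos did not pass (188 ± 176 against 388 ± 169, adjusted p = 0.183).

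**Figure D3:**
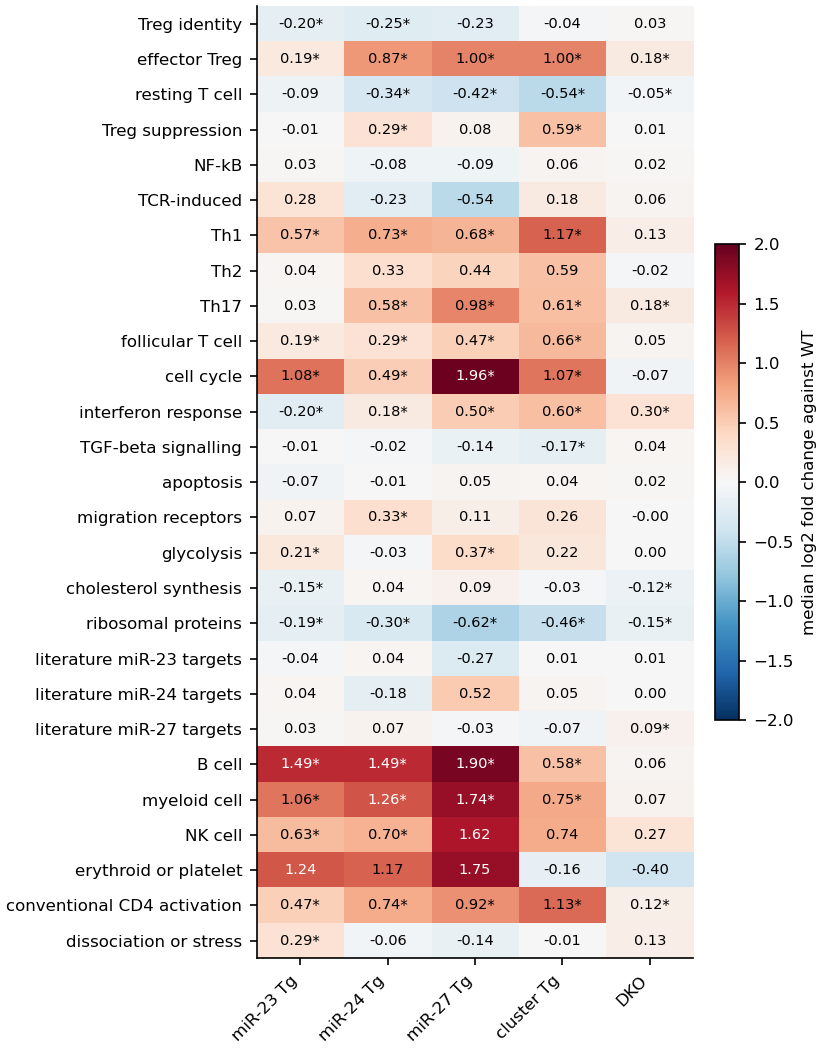
Median log2 fold change against WT of each gene list in each group, as a heat map with an asterisk where camera gave an adjusted p under 0.05. With an estimated correlation 0 of the lists passed in each comparison.

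The comparison of cluster Tg with WT asked what the 3 microRNAs together did. Ly6c2 rose 13.7-fold (34.9 ± 25.5 against 1.77 ± 0.660, adjusted p = 0.000129), and Dleu2, the host transcript of another microRNA cluster, rose 7.81-fold (20.04 ± 7.42 against 2.03 ± 0.250, adjusted p = 5.86e-06). Ppif fell 2.59-fold (9.21 ± 0.637 against 24.6 ± 1.35, adjusted p = 1.55e-06), and Ecm1 fell 2.23-fold (62.4 ± 7.59 against 140 ± 24.4). There were 1592 genes higher and 1214 lower, 404 and 124 of them by at least 2-fold. The other large rises were those of mucin gene Muc13 (7.98-fold), cell cycle inhibitor gene Cdkn2a (7.58-fold; 7.19 ± 6.05 against 0.344 ± 0.207), Krt17 (6.68-fold), galectin gene Lgals3 (6.22-fold; 20.5 ± 12.3 against 2.51 ± 0.552), Itgam (6.06-fold; 6.59 ± 3.05 against 0.601 ± 0.170, adjusted p = 8.19e-05) and transporter gene Slc15a3 (6.03-fold; 17.5 ± 8.79 against 2.28 ± 0.563). The large falls were those of Sh3bgrl2 (5.24-fold; 1.48 ± 1.10 against 8.79 ± 0.250), Gabrr2 (4.97-fold), Pydc3 (4.25-fold, adjusted p = 0.0302), transglutaminase gene Tgm2 (4.13-fold; 1.89 ± 0.267 against 10.5 ± 5.53), Tnnt2 (4.11-fold), Arhgap20 (3.58-fold), Sorcs2 (3.46-fold; 3.05 ± 1.40 against 11.2 ± 0.560) and Drc1 (3.43-fold). Without cluster Tg library 1 there were 865 higher and 602 lower.

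Effector Treg genes rose in 24 of 34 cases in cluster Tg and fell in 0 (limma; 10 did not pass), with Itgb1 3.56-fold higher (224 ± 46.5 against 62.3 ± 10.4), Il1rl1 4.59-fold (24.8 ± 9.67 against 4.77 ± 0.935) and Batf 2-fold (192 ± 27.8 against 95.5 ± 10.9). The list had adjusted p = 3.04e-14, and adjusted p = 0.234 with an estimated correlation. Interferon response genes rose in 27 of 43 cases, such as Ifih1 by 2.43-fold, Ly6a by 3.98-fold (464 ± 110 against 114 ± 6.32) and Ifit3 by 3.06-fold (adjusted p = 1.23e-11, and adjusted p = 0.276 with an estimated correlation). Of 45 cell cycle genes 23 rose, and Mki67 stood at 30.1 ± 1.67 against 9.31 ± 3.22 (adjusted p = 2.96e-09, and adjusted p = 0.561 with an estimated correlation). Ribosomal protein genes fell in 20 of 37 cases (adjusted p = 2.21e-09, and adjusted p = 0.329 with an estimated correlation), such as Rps20 by 1.68-fold (753 ± 134 against 1260 ± 180). Resting T cell genes fell in 15 of 22 cases and 1 rose, with Ccr7 1.98-fold lower (88.5 ± 15.3 against 174 ± 5.47), Bach2 2.15-fold lower and Dapl1 4.23-fold higher (adjusted p = 3.93e-06, and adjusted p = 0.256 with an estimated correlation). Follicular T cell genes rose in 8 of 13 cases, such as Slamf6 by 1.68-fold and Pdcd1 by 1.99-fold (adjusted p = 5.53e-07, and adjusted p = 0.0817 with an estimated correlation). Th1 genes rose in 9 of 17 cases, with Il18r1 4.07-fold higher (120 ± 23.3 against 29.0 ± 5.13; list adjusted p = 7.27e-06, and adjusted p = 0.284 with an estimated correlation), and Th17 genes in 6 of 15 (adjusted p = 0.000602, and adjusted p = 0.44 with an estimated correlation). Suppression genes rose in 8 of 18 cases and fell in 2, with Tigit 2.85-fold higher (211 ± 75.2 against 70.0 ± 4.86), Ebi3 2.35-fold higher and Lrrc32 1.93-fold lower (adjusted p = 0.0196, and adjusted p = 0.276 with an estimated correlation). Of 19 TGF-beta signalling genes 4 fell, such as Ski by 1.39-fold and Acvr1b by 1.8-fold (adjusted p = 0.0422, and adjusted p = 0.61 with an estimated correlation). Of 17 B cell genes 1 was higher, Ly6d (adjusted p = 0.0422, and adjusted p = 0.766 with an estimated correlation). Of 15 myeloid genes 2 were higher, Itgam and Cst3 (list median 0.751, adjusted p = 0.0422, and adjusted p = 0.742 with an estimated correlation), and Lyz2 did not pass at 7.96 ± 0.241 against 2.36 ± 0.565. When adjusted over the list alone, 27 effector Treg, 30 interferon response, 36 cell cycle, 11 follicular T cell, 11 Th1 and 8 Th17 genes were higher, and 27 ribosomal protein genes were lower.

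**Figure D4:**
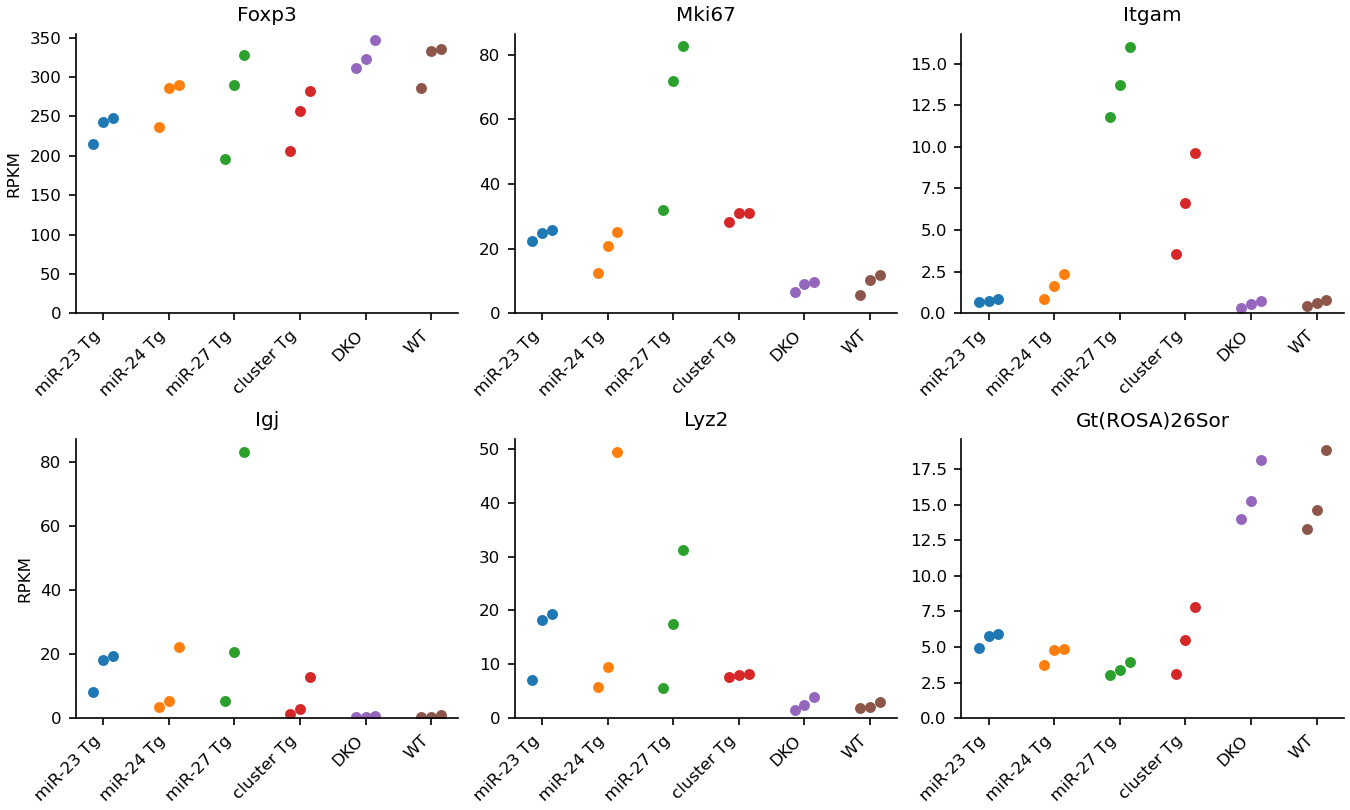
RPKM of Foxp3, Mki67, Itgam, Igj, Lyz2 and Gt(ROSA)26Sor by group, with a point per library sorted by value within its group. Gt(ROSA)26Sor lies at or under 7.84 RPKM in the 12 transgenic libraries and at or over 13.3 in the 6 others.

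The comparison of DKO with WT asked what the loss of the miR-23a and miR-23b clusters did. Actin-regulating gene Arpc1a, on chromosome 5 from 145083830 to 145108761, rose 1.57-fold (71.1 ± 3.73 against 45.1 ± 0.878, adjusted p = 0.00071). 2010111I01Rik, which spans 62964893 to 63326096 on chromosome 13 and holds the miR-23b cluster, rose 1.89-fold (100 ± 12.3 against 53.0 ± 7.98, adjusted p = 0.0155). It was named after its values were seen, since the rule for named genes skips such symbols. These were the 2 genes that limma called higher, 0 were lower, and 254 genes had an unadjusted p under 0.05. With only the DKO and WT libraries in the fit neither gene passed. 2010111I01Rik also did not pass with the replicate number as a block or in 4 of the 6 runs that left out 1 library. Among the genes that did not pass, Dffb was 1.32-fold higher (adjusted p = 0.176), Ccdc28b 1.45-fold higher (adjusted p = 0.176), Tfap4 1.21-fold lower (adjusted p = 0.555), Ndrg1 1.37-fold lower (adjusted p = 0.805) and Rps3a1 2.09-fold lower. None of the 43 interferon response genes passed over all genes, while 9 were higher when adjusted over the list alone. Their median was 0.30, with adjusted p = 6e-30 for the list, and adjusted p = 0.136 with an estimated correlation: Mx1 stood at 11.6 ± 1.58 against 5.10 ± 1.03, Oas2 at 10.8 ± 0.900 against 5.32 ± 0.835, Ifit3 at 13.8 ± 3.999 against 6.93 ± 0.592 and Mx2 at 5.34 ± 0.247 against 2.83 ± 0.668. For 34 effector Treg genes the median was 0.18 (adjusted p = 1.43e-07, and adjusted p = 0.652 with an estimated correlation), with Glrx at 51.6 ± 8.37 against 36.9 ± 2.59 and Maf at 64.2 ± 10.6 against 45.7 ± 2.01. The 37 ribosomal protein genes had a median of -0.15 (adjusted p = 9.97e-08, and adjusted p = 0.652 with an estimated correlation), and 22 reported miR-27 targets a median of 0.089 (adjusted p = 0.0269, and adjusted p = 0.673 with an estimated correlation), with Nfe2l2 at 19.7 ± 1.21 against 15.8 ± 0.736. Il21 stood at 5.31 ± 1.06 against 2.19 ± 0.757, Ppif at 31.7 ± 2.83 against 24.6 ± 1.35 (adjusted p = 0.805) and Gt(ROSA)26Sor at 15.8 ± 2.15 against 15.6 ± 2.89. Mki67 and Lyz2 did not pass in DKO, with Lyz2 at 2.68 ± 1.21 against 2.36 ± 0.565.

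Direct comparisons asked how miR-27 differed from the other members. Against miR-23 Tg, miR-27 Tg had 1431 genes higher and 1261 lower. Itgam was 11.3-fold higher (13.8 ± 2.12 against 0.758 ± 0.0784, adjusted p = 8.36e-06), costimulation gene Cd80 9.23-fold (21.6 ± 2.92 against 1.88 ± 0.160), Slc15a3 8.71-fold (18.7 ± 1.84 against 1.71 ± 0.176), Fads2 6.73-fold and Muc13 6.49-fold. Snhg9 was 7.11-fold lower, Tnfaip3 6.96-fold (95.8 ± 55.9 against 566 ± 84.8, adjusted p = 0.0387), Zbtb10 4.87-fold, C2cd4b 4.37-fold and Rhob 4.25-fold, and the calls of Tnfaip3 and Rhob ended with the level of immediate-early genes as a covariate. With that covariate 1409 of the 2692 calls stayed, and the 1283 that ended had a median absolute log2 fold change of 0.318 (0.447 before) and a median standard error of 0.139 (0.124 before). Without any 1 of the 6 libraries 942 to 1497 genes were higher and 825 to 1333 lower. Interferon response genes were higher in 33 of 43 cases (adjusted p = 8.02e-18, and adjusted p = 0.419 with an estimated correlation) and cell cycle genes in 5 of 45 (adjusted p = 2.5e-06, and adjusted p = 0.745 with an estimated correlation). Against miR-24 Tg, miR-27 Tg had 1518 genes higher and 1250 lower. Lgals7 was 7.25-fold higher, Itgam 6.99-fold (13.8 ± 2.12 against 1.63 ± 0.746), Pdlim4 6.99-fold, granzyme gene Gzmk 6.61-fold and Marcksl1 6.41-fold (62.4 ± 6.53 against 9.29 ± 0.632, adjusted p = 6.95e-07). Sytl4 was 5.17-fold lower, Lhfpl1 4.66-fold, Dapl1 4.26-fold (10.2 ± 3.19 against 43.8 ± 1.52), Xcl1 4.14-fold and Zbtb10 4-fold. Cell cycle genes were higher in 41 of 45 cases (adjusted p = 3.32e-15, and adjusted p = 0.721 with an estimated correlation). With only these 2 groups in the fit 524 genes were higher and 431 lower.

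Cluster Tg was also set against miR-27 Tg and against DKO. Against miR-27 Tg, 403 genes were higher and 386 lower. Snhg9 was 5.28-fold higher, Rasd1 4.08-fold, Dapl1 3.92-fold (41.2 ± 10.9 against 10.2 ± 3.19, adjusted p = 0.00149), clock gene Ciart 3.69-fold and Cd70 3.14-fold. Slpi was 5.65-fold lower, Myo6 3.74-fold (0.902 ± 0.263 against 4.77 ± 1.16, adjusted p = 0.000404), Pdlim4 3.03-fold, Tgm2 2.71-fold and Hap1 2.68-fold. Of 45 cell cycle genes 2 were lower (median -0.81, adjusted p = 9.7e-11, and adjusted p = 0.888 with an estimated correlation), and of 17 B cell genes 1 was lower (median -1.19, adjusted p = 8.71e-07, and adjusted p = 0.888 with an estimated correlation). With only these 2 groups in the fit 3 genes were higher and 2 lower, and the 786 calls that ended had the same median absolute log2 fold change of 0.481, with a median standard error of 0.116 (0.107 before). With the B cell covariate 18 were higher and 23 lower, and the 748 calls that ended went from 0.468 to 0.395, with a median standard error of 0.134 (0.108 before). All 789 kept their sign with the B cell covariate. With only the 2 groups in the fit the folds stay the same by construction, so their size and sign are no check there. Against DKO, cluster Tg had 1734 genes higher and 1338 lower. Ly6c2 was 16.0-fold higher (34.9 ± 25.5 against 1.39 ± 0.0913, adjusted p = 5.8e-05), Cdkn2a 9.32-fold, Dleu2 7.49-fold (20.04 ± 7.42 against 2.14 ± 0.257), Krt17 7.27-fold and Dapl1 7.19-fold (41.2 ± 10.9 against 5.24 ± 1.11). Pydc3 was 4.96-fold lower, Tgm2 4.87-fold (1.89 ± 0.267 against 11.4 ± 3.30), Gabrr2 4.56-fold, Sh3bgrl2 4.53-fold and Drc1 4.38-fold. Effector Treg genes were higher in 19 of 34 cases (adjusted p = 3.37e-08, and adjusted p = 0.454 with an estimated correlation) and resting T cell genes lower in 14 of 22 (adjusted p = 0.000302, and adjusted p = 0.454 with an estimated correlation). With only these 2 groups in the fit 837 genes were higher and 521 lower.

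The last comparison of this kind asked which changes were shared between genotypes. Itgam, Slc15a3 and Angptl2 were higher, and Ppif, Sh3bgrl2, Arhgap20 and Tnnt2 lower, in miR-27 Tg and in cluster Tg. In miR-27 Tg and cluster Tg 1030 genes were higher in each, 719 were lower in each and 13 moved in opposite directions. Across 11517 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.683, against 0.505 for simulated unchanged groups that shared the same WT libraries. The covariance was 0.298, 0.202 above the simulated value. For miR-24 Tg and cluster Tg r was 0.559, with a covariance 0.104 above the simulated one: Xcl1, Dapl1 and Krt17 were higher and Ecm1 and Gabrr2 lower in each. In that pair 360 genes were higher in each, 287 lower in each and 7 moved in opposite directions. For miR-24 Tg and miR-27 Tg 310 were higher in each, 205 lower in each and 36 opposite. For miR-23 Tg and cluster Tg r was 0.44, below the simulated 0.499, while the covariance was 0.144 against a simulated 0.0946. In this pair 14 genes were higher in each, 13 lower in each and 3 moved in opposite directions. The comparisons share the WT libraries, so some overlap of this kind arises without a shared effect. For DKO the covariance differed from the simulated one by -0.000531 with miR-23 Tg, -0.00651 with miR-24 Tg, -0.00285 with miR-27 Tg and -0.0196 with cluster Tg. By ranks the same pairs lay far from the simulated groups. Spearman rho was 0.098, 0.173, 0.148 and 0.003 in that order, against simulated values of 0.456 to 0.458. The simulation therefore did not match the ranks in these pairs, and the covariances alone do not show that DKO resembled an unchanged group.

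Genes with 3' UTR matches to nucleotides 2 to 8 of each microRNA were then compared with the other genes, which asks whether predicted targets were lower. Named genes with a miR-23 site that fell in miR-23 Tg were Sh3bgrl (1.49-fold; 37.5 ± 1.77 against 56.0 ± 0.883, adjusted p = 0.00488), Sft2d1 (1.61-fold, 2 sites), Zfp874a (1.62-fold, 2 sites), Zfp937 (1.7-fold, 2 sites) and Zfp758 (1.51-fold). Those with a miR-24 site that fell in miR-24 Tg were Ecm1 (4.3-fold), Lcn10 (3.24-fold), Ttyh3 (2.51-fold, 3 sites; 13.5 ± 2.25 against 34.3 ± 0.670), Prkar1b (2.46-fold) and lamin gene Lmna (2.4-fold). Those with a miR-27 site that fell in miR-27 Tg were Arhgap20 (4.62-fold), Sh3bgrl2 (4.6-fold), Cecr6 (3.32-fold), Osgin1 (2.77-fold; 7.07 ± 1.09 against 20.4 ± 2.50, adjusted p = 1.82e-05) and Wnt3 (2.7-fold). Several were not particular to a single member. Arhgap20 held a site of each member and also fell 2.34-fold in miR-24 Tg, where Osgin1 fell 2.3-fold. Lcn10 fell 2.92-fold in miR-27 Tg and Ecm1 1.59-fold in miR-23 Tg, and Sh3bgrl2 and Cecr6 also held a miR-24 site. Mean RPKM was low for Lcn10 (0.193 against 1.81), Prkar1b (0.659 against 2.30), Cecr6 (0.318 against 2.22) and Wnt3 (0.696 against 2.77). Of 21 genes with a 3' UTR that were lower in miR-23 Tg, 15 had a miR-23 site (71.4%, against 16.3% of all genes tested; Fisher's exact test two-sided, adjusted p = 1.83e-07). For miR-24 sites in miR-24 Tg it was 155 of 480 lower genes (32.3% against 19.1%; Fisher's exact test, adjusted p = 4.31e-11), and for miR-27 sites in miR-27 Tg 327 of 1357 (24.1% against 17.2%; Fisher's exact test, adjusted p = 4.31e-11). In cluster Tg 228, 306 and 269 of 1132 lower genes had a miR-23, miR-24 or miR-27 site (20.1%, 27% and 23.8%). Fisher's exact test takes genes as independent, so its p does not measure the spread between libraries.

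Over all genes the differences were small. The 1730 genes with a miR-23 site had a median log2 fold change 0.07 lower than the 8854 without in miR-23 Tg (difference -0.07), with 60.9% of site genes below 0 against 44.5%. This was the only 1 of 15 seed tests that passed (camera, adjusted p = 0.000458, and adjusted p = 0.637 with an estimated correlation). The difference was -0.046 for miR-24 sites in miR-24 Tg (adjusted p = 0.0984) and -0.078 for miR-27 sites in miR-27 Tg (adjusted p = 0.104). In cluster Tg it was -0.049, -0.06 and -0.064 for miR-23, miR-24 and miR-27 sites, and in DKO 0.018, 0.008 and 0.019. Without DKO library 1 the DKO differences turned to -0.023, -0.008 and -0.009, so their direction rests on that library. Site genes of the other members did not pass either: -0.014 for miR-24 and -0.032 for miR-27 sites in miR-23 Tg, 0.05 for miR-23 and 0.034 for miR-27 sites in miR-24 Tg, and 0.003 for miR-23 and 0.012 for miR-24 sites in miR-27 Tg. Against 10000 random lists matched on 3' UTR length and expression, the site genes of the overexpressed member lay lower in each single transgenic group. The differences were -0.043 in miR-23 Tg, -0.073 in miR-24 Tg and -0.087 in miR-27 Tg (two-sided against the random lists, adjusted p = 0.000333 each). The lists were drawn from genes, so this p does not measure the spread between libraries. It was equally low (adjusted p = 0.000333) for differences of only 0.015 and 0.016 for miR-23 and miR-27 sites in DKO. The sites of other members passed this test in the upward direction in 2 cases, at 0.028 for miR-23 sites in miR-24 Tg (adjusted p = 0.000333) and 0.013 for miR-24 sites in miR-23 Tg (adjusted p = 0.0108).

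**Figure D5:**
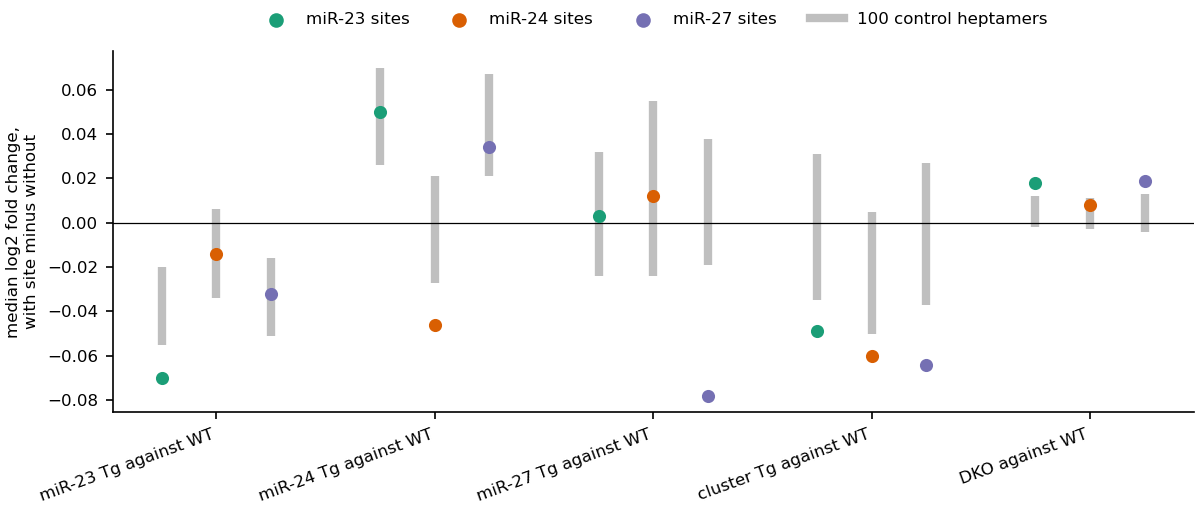
Median log2 fold change of genes with a seed site minus that of genes without, for 3 microRNAs in 5 comparisons with WT. Grey bars span the values of 100 control heptamers made of the bases of each site, and the site of the overexpressed microRNA lies below its bar in miR-23 Tg, miR-24 Tg and miR-27 Tg.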

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

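The tests of sex in this part were chosen after the data were seen, because the labels give no sex and it was read from the X- and Y-linked genes. Of the 3 libraries per group 2 were male and 1 female in miR-23 Tg and miR-27 Tg, and 1 male and 2 female in the other groups, so sex was unbalanced between these 2 groups and WT. A model with an interaction of genotype and sex asked whether the difference from WT differed between female and male libraries. It did for 5 genes in miR-23 Tg (Slc14a1 and the small RNA genes Mir1940, Mir212, Mir7044 and Mir7091), 3 genes in miR-24 Tg (Mir212, Mir7044 and Mir7091), 8 genes in miR-27 Tg (Acsbg1, Mapre3, Slc27a1 and 5 small RNA genes) and 4 genes in cluster Tg (Mir191, Mir1940, Mir212 and Mir363). In DKO limma called 0, with 649 genes at an unadjusted p under 0.05. Without small RNA entries limma called 0 genes in each of miR-23 Tg, miR-24 Tg, miR-27 Tg and cluster Tg. With all entries kept, 617, 569, 1665 and 1424 genes had an unadjusted p under 0.05 there. All of these differences rest on the same WT libraries, of which 1 was male. The difference of Mir7044 was the same (7.29 on the log2 scale) in miR-23 Tg, miR-24 Tg and miR-27 Tg, where it was listed at 0, so it comes from the WT libraries alone, and Mir212 and Mir7091 also recur between genotypes. These results are therefore not evidence of separate effects of sex in each genotype. Some combinations of genotype and sex held 1 library, whose spread was assumed to be that of the others.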

How the results depend on the processing

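The covariates for sex, B cell genes and immediate-early genes, the run without small RNA entries and the run without 2 libraries were chosen after the data were seen. Named gene results were counted once per gene, comparison and alternative. Under the alternatives other than leaving out each library in turn, 3702 of them stayed on the same side of the threshold. Those that passed also kept their direction, while changes of direction among results that did not pass were not counted. Of the others, 51 passed only under the alternative, 202 no longer passed and 2 reversed. These alternatives include the fits with only the 2 compared groups, which cannot change a direction, and the run without 2 libraries. Of the list results, 357 were the same, 114 no longer passed and 4 reversed. With 1 library left out, 2032 gene results were the same, 10 passed only then and 232 no longer passed, and for lists 351 were the same and 33 no longer passed. The tests used RPKM and not counts, and median-of-ratios factors of 0.988 to 1.019 moved little. Where a value below differs, the cause was not tested.

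Counts are given as higher and lower. With a pseudocount of 1, miR-23 Tg against WT had 11 and 15. With only the 2 groups in the fit, 118 genes were higher in miR-23 Tg, 284 higher and 271 lower in miR-24 Tg, 656 lower in cluster Tg, and 1 higher and 2 lower in DKO, each against WT. The same setting gave 524 and 431 for miR-27 Tg against miR-24 Tg, 3 and 2 for cluster Tg against miR-27 Tg, and 837 and 521 for cluster Tg against DKO. With the replicate block, miR-23 Tg had 38 and 38 and DKO 1 higher. The sex covariate gave 8 and 12 for miR-23 Tg, and 266 and 243 for cluster Tg against miR-27 Tg. The B cell covariate gave 2 and 1 for miR-23 Tg, 232 and 214 for miR-24 Tg, 454 and 276 for miR-27 Tg, and 18 and 23 for cluster Tg against miR-27 Tg. The immediate-early covariate gave 188 and 83 for miR-23 Tg, 744 lower for miR-27 Tg against miR-23 Tg, and 263 and 229 for cluster Tg against miR-27 Tg. Without the 2 libraries with the highest B cell and myeloid markers there were 262 and 318 for miR-24 Tg, 791 lower for miR-27 Tg against miR-23 Tg, 778 and 603 for miR-27 Tg against miR-24 Tg, and 162 and 153 for cluster Tg against miR-27 Tg.

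With an estimated correlation 0 lists passed in each of the 5 comparisons with WT, and with fry 0 in miR-23 Tg, 20 in miR-27 Tg and 0 in DKO. Under the B cell covariate the log2 fold changes of Lyz2 (-0.127) and C1qa (-0.07) in miR-27 Tg turned negative, as did the medians of the B cell (-0.031) and myeloid (-0.118) lists in miR-23 Tg, cell cycle in miR-24 Tg (-0.019) and myeloid in miR-27 Tg (-0.18). With an 8-base match, seed differences that newly passed were -0.048 for miR-27 sites in miR-23 Tg, -0.036 for miR-24 sites in miR-24 Tg, -0.123 for miR-27 sites in miR-27 Tg, -0.08 and -0.095 for miR-23 and miR-27 sites in cluster Tg, and 0.025 and 0.032 for them in DKO. In miR-23 Tg the miR-23 difference was -0.07 with an estimated correlation and -0.053 with the B cell covariate, and neither passed. Against the matched background the differences that newly passed were 0.028 for miR-23 sites in miR-24 Tg, -0.073 and -0.087 for the own sites of miR-24 Tg and miR-27 Tg, -0.039, -0.05 and -0.055 in cluster Tg, and 0.015 and 0.016 for miR-23 and miR-27 sites in DKO, and that of miR-24 sites in miR-23 Tg turned to 0.013. Over genes with a mean of at least 5 RPKM, r of miR-27 Tg and cluster Tg was 0.64.

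With each library left out in turn, counts ranged from 1 to 3 higher and 1 to 3 lower in miR-23 Tg, 264 to 470 and 255 to 377 in miR-24 Tg, 1342 to 1884 and 965 to 1571 in miR-27 Tg, 865 to 1644 and 602 to 1248 in cluster Tg, and 1 to 2 and 0 to 1 in DKO. They ranged from 942 to 1497 and 825 to 1333 for miR-27 Tg against miR-23 Tg, 937 to 1664 and 764 to 1400 against miR-24 Tg, 131 to 551 and 137 to 668 for cluster Tg against miR-27 Tg, and 1047 to 1822 and 773 to 1411 against DKO. Lists past the threshold numbered 14 to 16, 14 to 17, 12 to 15, 11 to 13 and 5 to 13 in miR-23 Tg, miR-24 Tg, miR-27 Tg, cluster Tg and DKO. Seed differences for miR-23, miR-24 and miR-27 sites ranged from -0.092 to -0.05, -0.025 to 0.005 and -0.041 to -0.015 in miR-23 Tg, and from 0.035 to 0.065, -0.06 to -0.037 and 0.028 to 0.053 in miR-24 Tg. In miR-27 Tg they ranged from -0.02 to 0.021, -0.003 to 0.028 and -0.092 to -0.056, in cluster Tg from -0.076 to -0.038, -0.081 to -0.054 and -0.075 to -0.052, and in DKO from -0.023 to 0.053, -0.008 to 0.04 and -0.009 to 0.05. For the fold changes of miR-27 Tg and cluster Tg r ranged from 0.628 to 0.726.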

Other observations

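The tests of sex, immediate-early genes, B cells, control heptamers, carrier libraries and Gt(ROSA)26Sor in this part were chosen only after the results were seen. Several lists have not been described yet. Th2 genes rose in 5 and fell in 2 of 11 cases in miR-27 Tg (list adjusted p = 0.1), with Il1rl1 4.03-fold higher (20.7 ± 3.99 against 4.77 ± 0.936) and Il17rb 2.68-fold higher. Migration receptor genes rose in 7 and fell in 3 of 26 cases in miR-24 Tg (adjusted p = 0.0178, and adjusted p = 0.259 with an estimated correlation), with Itga6 1.69-fold lower, and in 10 and 4 cases in miR-27 Tg (adjusted p = 0.182). Conventional CD4 activation genes rose in 7 of 11 cases in cluster Tg (adjusted p = 7.31e-05, and adjusted p = 0.276 with an estimated correlation), with Tnfsf11 2.95-fold higher (66.6 ± 16.4 against 21.8 ± 1.08). Glycolysis genes rose in 10 and fell in 3 of 21 cases in miR-27 Tg (adjusted p = 0.0238, and adjusted p = 0.403 with an estimated correlation), with Aldoc 2.26-fold higher and Pdk1 2.18-fold lower (14.4 ± 1.35 against 31.8 ± 1.82). NF-kB genes rose in 3 and fell in 3 of 29 cases in miR-27 Tg (adjusted p = 0.375), with Birc3 1.66-fold lower and Malt1 1.64-fold higher. TCR-induced genes rose in 4 and fell in 4 of 29 cases there (adjusted p = 0.102), with Egr2 1.57-fold higher and Dusp2 2.17-fold lower, and TGF-beta signalling genes rose in 2 and fell in 5 of 19, with Smad7 1.94-fold lower.

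Of 13 literature miR-23 targets limma called 0 in miR-23 Tg (adjusted p = 0.07 for the list), with Ppif at 19.6 ± 0.829 against 24.6 ± 1.35. Of 12 literature miR-24 targets 3 fell in miR-24 Tg (adjusted p = 0.0981), namely H2afx by 2.07-fold (10.6 ± 2.40 against 22.2 ± 2.28), Acvr1b by 1.43-fold and Myc by 1.34-fold. In cluster Tg the median of the literature miR-23 targets was 0.01 and their mean -0.107. Cholesterol synthesis genes had a median of -0.121 in DKO (adjusted p = 0.000919, and adjusted p = 0.652 with an estimated correlation). Dissociation or stress genes had a median of 0.289 in miR-23 Tg (adjusted p = 0.0179, and adjusted p = 0.532 with an estimated correlation), with Hspd1 at 71.6 ± 15.6 against 54.8 ± 4.09. The miRNA cluster loci list rose in 4 of 6 cases in cluster Tg (adjusted p = 0.0473, and adjusted p = 0.284 with an estimated correlation). The erythroid or platelet list did not pass in the 5 comparisons with WT, with Hbb-b1 at 49.1 ± 50.8 in miR-27 Tg against 4.93 ± 6.80 (list adjusted p = 0.417), and of its genes Itga2b fell 1.6-fold in cluster Tg. The sex-linked list did not pass either (adjusted p = 0.715 in miR-27 Tg). The plasma cell and CD8 T cell lists had too few tested genes: Igj stood at 15.3 ± 6.18 in miR-23 Tg against 0.454 ± 0.341 in WT, and Cd8a at 3.90 ± 0.223 in miR-24 Tg against 1.98 ± 0.817. Cd8b1, the other CD8 gene, differed little, at 16.38, 15.32 and 15.09 in the miR-24 Tg libraries against 14.89, 15.45 and 15.16 in WT.

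Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and in each of the 9 only the real split (1 of 10) gave as many genes. The real counts and the highest of the other splits were 41 and 1 for miR-23 Tg, 1034 and 1 for miR-24 Tg, 3294 and 0 for miR-27 Tg, 2806 and 0 for cluster Tg, and 2 and 0 for DKO, each against WT. They were 2692 and 1 for miR-27 Tg against miR-23 Tg, 2768 and 52 against miR-24 Tg, 789 and 24 for cluster Tg against miR-27 Tg, and 3072 and 0 for cluster Tg against DKO.

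The first pattern weighed was the large number of genes changed in miR-27 Tg against WT. Of the 3294 genes, 2949 still passed in the same direction with the sex covariate, 2504 with the immediate-early covariate and 706 with the B cell covariate. This argues against each covariate, as fitted alone, as the whole cause. A score that tracks its cause imperfectly would also leave calls. Sex and B cell score were entangled: males scored above females in each transgenic group (miR-27 Tg female -0.1, males 1.17 and 1.89). In DKO the male scored lowest (-0.98 against -0.69 and -0.92). Fits with a single covariate therefore do not separate sex from B cells. Among the 17 tested genes of the B cell list the median correlation within groups was 0.813 (highest of 1000 random lists 0.333). This points to B cells or their RNA among the sorted cells, although the CD4 and CD25 sort would remove them. For the 15 myeloid genes the median correlation was 0.609, also above those random lists, so B cells need not be the only other cells. No covariate for myeloid genes was fitted. In miR-27 Tg, Cd74 stood at 359 ± 92.7 against 109 ± 23.7, H2-Aa at 69.4 ± 36.8 against 20.5 ± 7.22 and Cd79a at 10.2 ± 6.77 against 1.60 ± 0.732, and 9 of the 17 genes also reached 1 RPKM in WT. Whether the 2588 calls that ended with this covariate come from B cells was left open, since their median absolute log2 fold change went from 0.51 to 0.407 while their median standard error went from 0.131 to 0.194.

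The second pattern was that genes with sites of the overexpressed microRNA were lower. Base composition as the whole cause is argued against, since 0, 0 and 0 of 100 control heptamers lay as low as the miR-23, miR-24 and miR-27 sites in their own transgenic groups. The control medians were -0.041, -0.003 and 0.009 against -0.07, -0.046 and -0.078 for the sites, so in miR-23 Tg much of the difference was shared by controls. The length of the 3' UTR and expression as the whole cause are argued against by the differences of -0.043, -0.073 and -0.087 from matched random lists, although in miR-23 Tg matching made the difference smaller (-0.07 before). The transgenic microRNA itself is a candidate explanation that was left open. The 6 libraries that carry it had lower site scores than the 12 others for each of the 3 microRNAs (exact permutation over 18564 splits, two-sided, adjusted p = 0.00151 each), but they are the libraries in which the pattern was seen, so this restates it and supports nothing further, and most camera tests of the same genes did not pass.

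The third pattern was the lower Gt(ROSA)26Sor in the 4 transgenic groups. Sex is argued against, because the fall passed in 4 of the 4 comparisons with the sex covariate, and a fall of the region is argued against, because the lowest of 16 neighbouring genes was at -0.85 while Gt(ROSA)26Sor itself lay at -1.40 or lower. A transgene placed at this locus was left open: pooling the 12 transgenic libraries against the 6 others (exact permutation, two-sided, p = 5.39e-05) restates the fall that was already seen and adds no support. The labels do not say where the transgenes were inserted, and no biological explanation was tested.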
